A study of Tachysurus fulvidraco x Tachysurus vachelli with 6 samples.

How the data were processed

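Liver RNA of juvenile hybrid yellow catfish was profiled in 6 libraries, 3 from fish on a normal fat diet (NFD) and 3 from fish on a high fat diet (HFD), each after 60 days of feeding. The diet of each library was taken from its label, as was its replicate number. The composition of the diets is not given in the sources used here. Per the labels' protocols, total RNA was taken from frozen liver by a phenol-based reagent, RNA of mixed groups went into the libraries, and both long RNA and small RNA libraries were made for Illumina sequencing. How many fish stand behind a library is not given in the sources used here, so every p-value below measures the spread between these libraries, which may be pools of fish or partly technical.

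The mRNA values are RPKM, reads scaled to gene length and to the mapped reads of the library, as computed and deposited by the authors, per the file headers. Each row carries an identifier in the style of a Trinity de novo assembly, and the values have 2 decimals. The files used do not pair these identifiers with gene names, and no reference annotation was used here. The miRNA values are a signal of normalized read counts, also computed and deposited by the authors, per the file headers, with a name and a sequence for each row. Names carry the species prefix of the matched reference miRNA and, at their end, differences in length or sequence from it. Candidate miRNAs have names that start with PC. The submitters' processing notes name cutadapt, an adapter trimmer, and FastQC, a read quality tool, with no versions. The assembler settings, mapper, counter, reference database and scaling are not given in the sources used here.

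The mRNA table held 125223 identifiers in 69979 assembly components, a component being the part of an identifier before its last gene number. Identifiers of a shared component are often near-identical copies or alleles, between which a read counter has to choose, so their RPKM can shift from copy to copy. The miRNA table held 1200 names and 1119 distinct sequences, of which 655 names were candidates. In it, 77 sequences were listed under more than 1 name, 158 rows in all, and such rows repeated the same values. Sums and shares were therefore taken over distinct sequences. Besides these, dre-miR-122_R+2_1 and dre-miR-122_R+2_2 had different sequences but the same values in every library. They were counted as 2 sequences, also in the list for liver lipid metabolism.

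Depth was read from the values. In the miRNA table most low values were multiples of a step that was particular to the library. It was 0.842, 0.42 and 0.189 normalized counts in NFD replicates 1 to 3 and 0.644, 0.646 and 0.774 in HFD replicates 1 to 3. Many low values were even multiples of the step, so it may be a fraction of 1 read rather than 1 read. Of the values below 100, between 96.4% and 98.2% per library were whole multiples within 0.006 normalized counts. Because the rest were not whole multiples, the table was not treated as counts and no count test was run on it. The listed miRNAs summed to about 2840000, 6240000 and 14240000 steps in NFD replicates 1 to 3. In HFD replicates 1 to 3 they summed to 4390000, 4270000 and 3170000 steps. These are upper estimates of the reads, since a step may be less than 1 read. For mRNA, the commonest ratio of 2 libraries' RPKM over identifiers from 2 to 20 RPKM gave the relative number of mapped reads, 1, 0.91 and 1.01 in the NFD libraries and 0.86, 1.09 and 0.96 in the HFD libraries, relative to NFD replicate 1. These ratios disagreed between pairs by at most 0.002 on the log2 scale. The absolute mRNA depth is not given in the sources used here.

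Both tables were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all rows tested and a threshold of 0.05 on the adjusted p. The response was log2(RPKM + 1) for the 101810 identifiers with a mean of at least 0.5 RPKM, and log2(normalized count + 1) for the 304 miRNA rows with a mean of at least 10. Those 304 rows held 257 distinct sequences and 26 candidate rows. Fold changes are on these log2 scales with a pseudocount of 1, which understates the change of low rows. All 6 libraries entered each fit without a block. Figures and depth values were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

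The tests, thresholds, lists, naming rule and alternatives were fixed before the data were examined, apart from those named as later choices. The naming rule took, for miRNAs, up to 10 rises and 10 falls with the largest change past the threshold, filled up by the smallest p and named as not passing, all members of the miR-122, miR-33, miR-34 and miR-27 families, and up to 4 members with the smallest p from each list. For mRNA it asked for annotated genes, and without gene names only the 2 identifiers with the largest rise and the 2 with the largest fall among those whose diets did not overlap are printed. The rule's always-named metabolic genes could not be looked up.

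There were 7 miRNA lists, for liver lipid metabolism, the let-7 family, blood and immune cells, muscle, pancreas, endothelium and connective tissue, and epithelium. Members matched by family number in any species. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, and with Benjamini-Hochberg adjustment over the lists. An estimated correlation and limma's fry were added as later choices for these lists. A further 31 mRNA lists and 48 pairs of a miRNA and a target gene had also been fixed, and neither could be used without gene names.

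The scripts were tested on simulated data. In 1 table of 304 simulated miRNA rows, 10 rows were changed at each size. Changes of 1, 2 and 4 on the log2 scale were called in 40%, 80% and 100% of the changed rows. Of the 24 calls 2 were false. With 101810 simulated mRNA rows, changes of 2, 4 and 8 were called in 1.5%, 46.3% and 97%, and 5 of the 101 calls were false. In 50 simulated tables a lowered list was called in 100% of the tables and the other lists in 0.3% of their tests. In all of these simulations rows were drawn independently of one another, from a normal distribution around each row's mean. No simulated row was set to exactly 0 in a diet, and no reads moved between copies. The share of false calls may therefore differ in the real values.

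Alternatives were other pseudocounts, filters, normalizations and variance models, a replicate block, the removal of each library in turn and, for mRNA, an unadjusted threshold. Sums over components and 1 row per miRNA sequence were chosen after seeing the data. All tests of explanations were written after the values they bear on had been seen. The test that set miR-144 against miR-451 was also changed more than once after its values were seen. It first compared miR-144-3p with the main miR-451 sequence by an exact permutation test, which with 3 libraries against 3 cannot go below 0.1 and so could not have decided. A limma interval of the averaged difference, -1.65 to -0.21, was tried next. The rule used here rests on 95% intervals of 3 versions of that difference, each from the spread of its own 6 values, and all 3 were required to exclude 0.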

Results

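The data describe the liver of juvenile hybrid yellow catfish, a cross of Tachysurus fulvidraco and Tachysurus vachelli, after 60 days on a normal fat diet (NFD, 3 libraries) or a high fat diet (HFD, 3 libraries). Messenger RNA was measured as RPKM of de novo assembled genes, and microRNAs (miRNAs), short RNAs that repress messenger RNAs, as normalized read counts. The series concerns miRNAs and mRNAs of the liver under high dietary fat. The question that the design answers is which of them differ between these libraries of each diet. How many fish stand behind a library is not given in the sources used here.

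The hepatocyte miRNA miR-122-5p held 25.6%, 31.1% and 27% of the miRNA signal in NFD replicates 1 to 3 and 32.5%, 32.3% and 32.2% in HFD replicates 1 to 3. The 10 most abundant sequences held between 65.7% and 71.2% of the signal in each library. The estimates of miRNA depth ran from at most about 2840000 reads in NFD replicate 1 to at most 14240000 in NFD replicate 3. The HFD libraries held at most 3170000 to 4390000. These are upper estimates, since the unit that was counted may be a fraction of 1 read. That fraction could differ between libraries, so the estimates need not rank them by depth. Between 548 and 668 miRNA names were above 0 in a library. For mRNA, 76975, 78849 and 90539 identifiers were above 0 in the NFD libraries and 69162, 70900 and 78846 in the HFD libraries, at a relative depth that differed by at most 1.27-fold.

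Across rows, the libraries correlated between 0.95 and 0.99 for miRNA and between 0.57 and 0.73 for mRNA on the log2 scale. These correlations are over rows of a table, which are not independent replicates. The median correlation for miRNA was 0.972 within a diet and 0.958 between diets, and for mRNA 0.677 and 0.659. When RPKM was summed over the identifiers of a component, the mRNA correlations lay between 0.65 and 0.82.

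**Figure D1:**
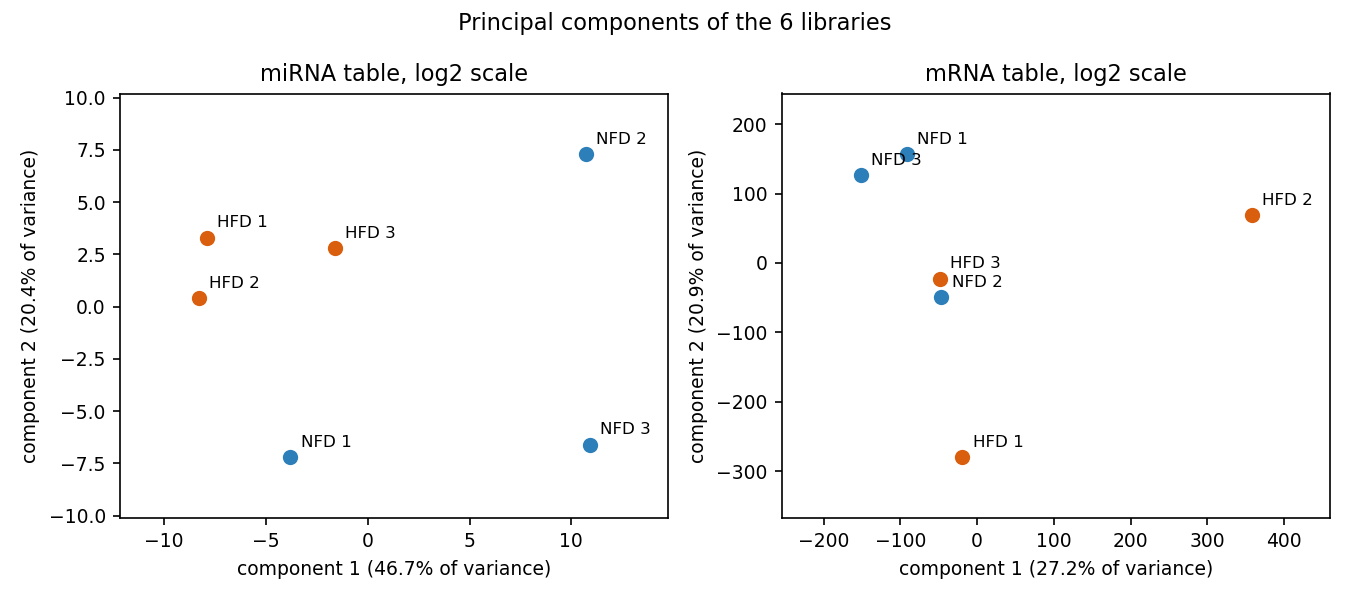
Principal components of the 6 libraries from log2 values, for miRNA (left) and mRNA (right), with 1 point per library coloured by diet (blue NFD, orange HFD) and axes in component units with their share of the variance. Component 1 held 46.7% of the miRNA variance and 27.2% of the mRNA variance. On the first miRNA component NFD replicate 1, at -3.8, lay within the HFD range of -8.3 to -1.6. NFD replicates 2 and 3 lay at 10.7 and 10.9 there. HFD replicate 2 stood apart on the first mRNA component at 357.7, where the other libraries lay between -151.8 and -19.4.

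The miRNAs that fell on the high fat diet were miR-144, miR-451 and miR-2188. miR-144 and miR-451 are transcribed together and are abundant in red blood cells. miR-144-3p fell 4.7-fold, from 1769 ± 976 to 353 ± 103 normalized counts (SD, n = 3 each), and miR-144-5p fell 3.17-fold, from 1127 ± 238 to 352 ± 51.7. miR-451 fell 2.06-fold, from 51486 ± 3736 to 25163 ± 4236, and was by far the more abundant. miR-2188-3p fell 2.36-fold, from 1159 ± 220 to 487 ± 43.8, and miR-2188-5p fell 2.07-fold, from 4914 ± 463 to 2390 ± 376.

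In limma's test with Benjamini-Hochberg adjustment over the 304 rows, 7 rows passed. They held 5 of the 257 distinct sequences, because both miR-144 sequences were listed under 2 names. The log2 differences were -1.67 with an adjusted p of 0.0302 for miR-144-5p (standard error 0.24), -1.04 with 0.0432 for miR-451 (0.17), -1.24 with 0.0436 for miR-2188-3p (0.22), -2.23 with 0.0436 for miR-144-3p (0.41) and -1.05 with 0.0478 for miR-2188-5p (0.20). For each of the 5 all HFD libraries lay below all NFD libraries. That separation was seen for 40 of the 257 sequences, or 15.6%, where chance gives 10%. No miRNA row rose past the threshold (0 of 304, limma), and 9 rows rose and 23 fell at an unadjusted p under 0.05, where 15 in all would be expected by chance.

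These calls sit close to the threshold. With 1 row per sequence 0 sequences passed (limma), with 27 of the 257 at an unadjusted p under 0.05 in the fit of all rows, and the adjusted p of the 5 was then 0.0575 to 0.0583. Leaving out 1 library at a time left 2, 9 and 0 rows without NFD replicates 1, 2 and 3, and 2, 0 and 1 without HFD replicates 1, 2 and 3, and only without NFD replicate 2 did the 7 rows pass again. The 2 rows without HFD replicate 1, let-7d-5p and the aca form of miR-125a-5p, and the 1 without HFD replicate 3, candidate PC-5p-30760_264, were higher in HFD.

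**Figure D2:**
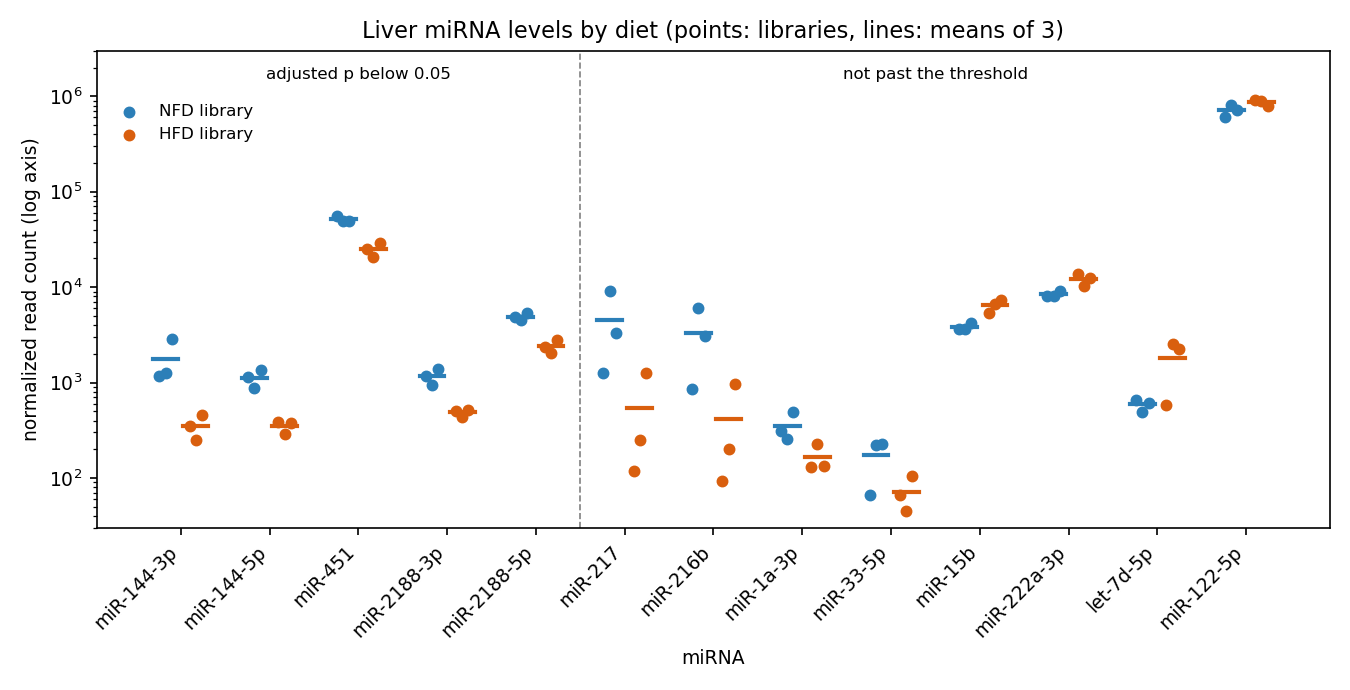
Normalized read counts on a log axis for 13 miRNAs, with a point per library (blue NFD, orange HFD) and a line at the mean of 3 libraries. The 5 miRNAs left of the dashed line passed the threshold in the adjustment over all 304 rows, each with all HFD points below all NFD points. At the right, miR-122-5p lay at 717475 in NFD and 868365 in HFD on average and did not pass.

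Other named miRNAs did not pass, and their values are given as such. On the lower side in HFD were 3 further miR-451 sequences, among them dre-mir-451-p3 (623 ± 198 in NFD, 250 ± 76.0 in HFD, adjusted p 0.210) and aca-miR-451-3p (183 ± 67.9 and 76.3 ± 12.4, adjusted p 0.251). miR-217 and miR-216b, which are abundant in exocrine pancreas, were at 4526 ± 4015 and 3326 ± 2622 in NFD and 541 ± 621 and 420 ± 475 in HFD. Their log2 differences were -3.32 and -3.25, each with an adjusted p of 0.285, and ran from -4.28 to -2.57 and from -4.18 to -2.51 when each library was left out. On the higher side were miR-15b (3838 ± 360 and 6482 ± 997, adjusted p 0.210), miR-222a-3p (8478 ± 645 and 12150 ± 1711, 0.371) and miR-221 (7948 ± 242 and 10383 ± 1521, 0.566). miR-125a-5p of the aca reference and let-7d-5p had log2 differences of 1.52 and 1.35 with adjusted p of 0.396 and 0.421, and in both HFD replicate 1 lay with the NFD libraries. Candidate PC-5p-30760_264 was listed at 0 in the NFD libraries and HFD replicate 3, and at 70.9 and 123 in HFD replicates 1 and 2 (adjusted p 0.405).

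In the fixed list for liver lipid metabolism, 0 of 53 sequences passed over all rows (limma), and 0 adjusted over the list alone. Of the 53, 2 had an unadjusted p under 0.05. miR-144, which passed, was not on this list. It stood among the fixed target pairs with the gene abca1, and that pair could not be tested. miR-122-5p differed by 0.28 on the log2 scale with an adjusted p of 0.515. miR-33-5p, which lies within genes of sterol regulators and represses cholesterol export, was at 173 ± 92.0 in NFD and 72.0 ± 29.6 in HFD, a log2 difference of -1.13 with an adjusted p of 0.566. Its other arm differed by 0.03. miR-34a was at 2027 ± 362 and 2228 ± 72.8 (0.15, adjusted p 0.839), and miR-27b-3p at 18107 ± 7136 and 17699 ± 2045 (0.05, adjusted p 0.94). miR-21b-3p had a log2 difference of -0.88 with an adjusted p of 0.349. Of the 53 sequences 34 were higher and 19 lower, with a median of 0.10, and the list's adjusted camera p was 0.277, or 0.730 as the adjusted p with an estimated correlation.

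Of the 7 miRNA lists, the blood and immune cell list was called by camera as lower in HFD, with an adjusted p of 0.000134. The call was lost with an estimated correlation of 0.27 between its members, at an adjusted p = 0.730 with that estimated correlation. It was also lost without NFD replicate 1, at an adjusted camera p of 0.0851. Camera called at least 1 list in 8 of the 10 splits of the 6 libraries 3 against 3. Of its 15 sequences, 8 were lower and 7 higher, 3 passed over all rows and 6 adjusted over the list alone, with a median log2 difference of -0.41. Those 6 were both arms of miR-144 and 4 miR-451 sequences. miR-150, miR-146 and miR-155, which are abundant in immune cells, had differences of 0.35 for miR-150-5p, 0.22 for miR-146a and 0.72 for miR-155, and miR-142a-5p had -0.41 and miR-142b-3p 0.25, none past the threshold. These members were chosen after their values were seen. Left-out libraries moved these values: without NFD replicate 2 they were -0.46 for miR-155, 0.06 for miR-146a, -0.84 for miR-142a-5p and -0.14 for miR-142b-3p, and without NFD replicate 3 miR-142a-5p was at -0.04.

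The other lists were not called. The pancreas list had 1 of 6 sequences higher and 5 lower, a median of -0.44 and an adjusted camera p of 0.224, and 2 sequences, miR-217 and miR-216b, passed when adjusted over the list alone and 0 over all rows. The muscle list had 3 of 5 lower, a median of -0.61 and an adjusted p of 0.224, with miR-1a-3p at 352 ± 124 and 165 ± 55.9, and 0 passed over all rows or adjusted over the list alone, with 2 at an unadjusted p under 0.05. The endothelium and connective tissue list had 10 of 16 lower, a median of -0.12 and an adjusted p of 0.386, with miR-143-5p at -0.59 and miR-126-3p at -0.22. The epithelium list had 6 of 9 higher, a median of 0.17 and an adjusted p of 0.453, with miR-194a-5p at 0.29. The let-7 list had 8 of 15 lower, a median of -0.05, a mean of 0.04 and an adjusted p of 0.750. In each of these 3 lists 0 sequences passed limma's test over all rows and 0 adjusted over the list alone, and 2, 0 and 1 had an unadjusted p under 0.05. With an estimated correlation the adjusted p of the lists other than lipid metabolism and blood ran from 0.730 to 0.897.

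**Figure D3:**
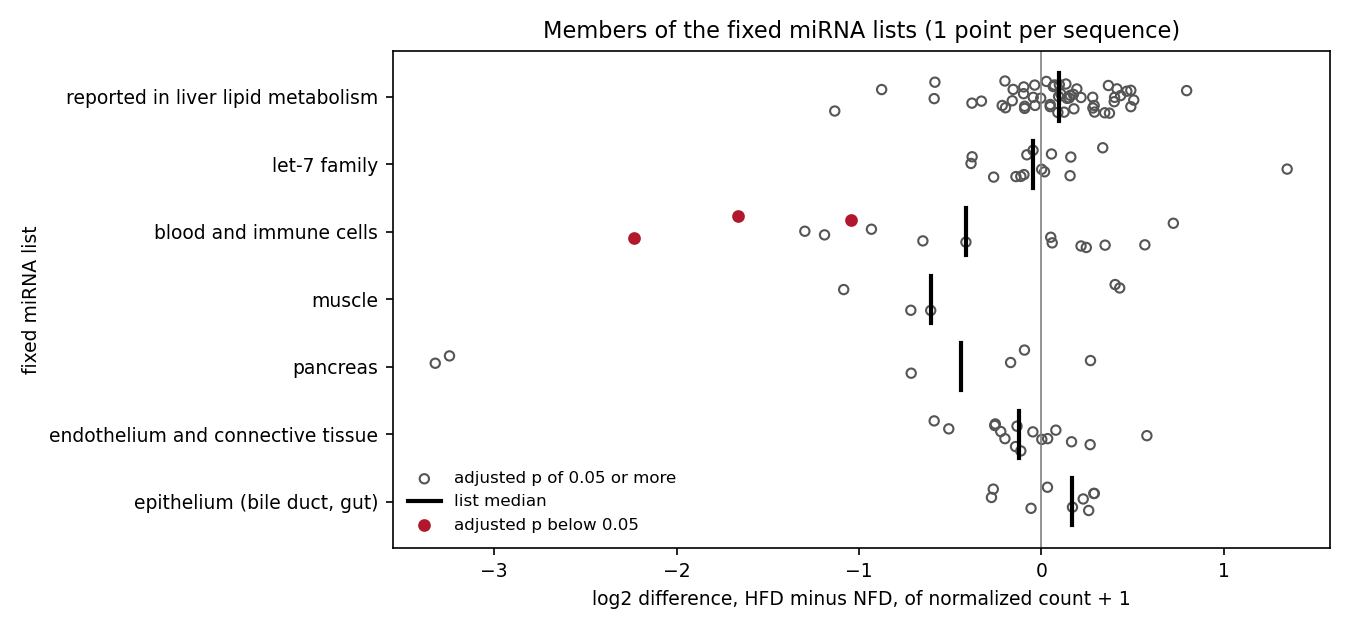
Log2 differences (HFD minus NFD) of the members of the 7 fixed miRNA lists, with a point per distinct sequence, filled where the adjusted p over all rows was below 0.05, and a bar at the list median. The 3 filled points are miR-144-3p, miR-144-5p and miR-451 in the blood and immune cell list, and the points at -3.32 and -3.25 in the pancreas list are miR-217 and miR-216b.

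For mRNA, 71 of 101810 identifiers differed between the diets in limma's test with Benjamini-Hochberg adjustment, 38 higher and 33 lower in HFD. At an unadjusted p under 0.05 there were 4952, where 5090 would be expected by chance. Most calls were on-off: 56 of the 71 were listed at 0 in every library of a diet, 29 of them in NFD and 27 in HFD. This rests in part on what the test can call. Among the simulated mRNA rows, changes of 2 on the log2 scale were called in only 1.5%, so smaller changes would mostly be missed. The calls therefore do not show how common on-off changes were among all changes. The files used do not pair identifiers with gene names, so what these genes do cannot be stated here. The largest rises were TRINITY_DN12983_c0_g1, listed at 0 in the 3 NFD libraries and at 1085.59, 1188.91 and 1119.19 RPKM in HFD replicates 1 to 3, and TRINITY_DN50989_c0_g1, listed at 0 in NFD and at 1098.64, 1116.8 and 1086.13 RPKM in HFD, each with an adjusted p of 3.19e-05. Both were the only identifier of their component.

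The largest falls were TRINITY_DN46671_c1_g5, at 218.77, 192.73 and 395.06 RPKM in NFD replicates 1 to 3 and listed at 0 in HFD (adjusted p 0.000566), and TRINITY_DN50934_c20_g10, at 500.2, 245.11 and 114.85 RPKM in NFD and listed at 0 in HFD (adjusted p 0.00427, and 0.0575 without NFD replicate 2). These belonged to components of 15 and 80 identifiers. Summed over the component, the first was at 1797 ± 312 RPKM in NFD and 1061 ± 181 in HFD, and the second at 14944 ± 2702 in NFD and 19078 ± 6410 in HFD (SD, n = 3). Of the 71 calls 38 shared a component with other identifiers, in 30 components, and 11 of those components passed when summed. The count moved to 22 with a pseudocount of 0.01, and to 30 without NFD replicate 1 and 44, 33 and 41 without HFD replicates 1, 2 and 3. Whichever library was left out, 22 to 27 of the 71 identifiers were called again.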

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

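Sums over components, 1 row per sequence and, for the lists, the estimated correlation and fry were chosen after seeing the data. For mRNA, 71 identifiers passed, and 51 to 87 did under pseudocount 0.1, both other filters, both rescalings, both other variance models and component sums. The count was 22 with a pseudocount of 0.01, 4809 with an unadjusted p and a 2-fold change, and 30 to 63 when each library was left out in turn, of which 22 to 27 were among the 71. For miRNA, 7 rows passed, and 6 or 7 did under other pseudocounts, a mean of at least 50, and rescaling by median-of-ratios or to a common sum. The count was 4 without a filter, 0 without a trend in eBayes, 0 with only the sequences that have 1 name and 0 with 1 row per sequence, and 0 to 9 when each library was left out. The adjusted p of the 5 sequences ran from 0.0187 to 0.226 over the left-out libraries. Of the lists 1 passed, and 0 did with an estimated correlation and 0 with fry's directional test (adjusted p 0.286 for the blood and immune cell list, and 0.00688 in its mixed test of change in either direction; neither compares the list with other rows), and 0 to 2 when each library was left out. The adjusted p of that list was 0.0851 without NFD replicate 1. Both miR-144 sequences entered the miRNA test under 2 names each. Repeats of rows with a small p ease the Benjamini-Hochberg adjustment, and 1 row per sequence removed them. The setting with only the sequences that have 1 name left miR-144 out. Fewer rows or libraries also enter some of the fits. Beyond that, the cause of these changes was not tested.

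The replicate numbers did not pair the libraries: deviations from the diet means of same-numbered libraries correlated at 0.01, -0.26 and -0.01 for miRNA and -0.03, 0.02 and 0.03 for mRNA. With the replicate number as a block, 19 mRNA identifiers and 0 miRNA rows passed, and 1 list was called.

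The log2 differences of the miRNAs and identifiers chosen by the naming rule were recomputed with pseudocount 0.1, without a filter, with median-of-ratios rescaling, with the block, for miRNA with 1 name or 1 row per sequence, and without each library, and not under the other settings. None reversed in these except without a library, where 10 of the rule's miRNAs that had not passed changed sign. Outside the rule, miR-155 ran from -0.46 to 1.59 and miR-142b-3p from -0.14 to 0.52. Forms of miR-146b changed sign too: dre-miR-146b from -0.39 to 1.18, cgr-miR-146b-5p from -0.23 to 0.32 and ssa-miR-146b-3p from -0.12 to 0.2. Over the left-out libraries the log2 difference ran from -0.05 to 0.34 for ssa-miR-122-2-3p, -0.37 to 0.24 for miR-33-3p, -0.01 to 0.81 for miR-499-5p, -0.52 to 0.41 for miR-27b-5p, -0.31 to 0.31 for miR-27b-3p, -0.16 to 0.36 for miR-27a-3p, -0.40 to 0.14 for miR-27e, -0.01 to 0.24 for miR-34a, -0.54 to 0.16 for miR-203-3p and -1.36 to 0.16 for miR-206-3p. Rescaling by median-of-ratios moved the median of all miRNA rows from 0.05 to 0.06 and that of mRNA from -0.02 to -0.04. The 31 mRNA lists, the 48 target pairs and their alternatives were not run for lack of gene names, and count tests (edgeR, DESeq2) were not run for lack of counts. Depth limits the rows near a few reads, by the upper estimates most in NFD replicate 1, where 1 read was worth at least 0.842 normalized counts.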

Other observations

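Pancreas miRNAs differed widely between libraries of a diet. In many fishes pancreatic tissue lies within or along the liver. miR-217 was at 1260, 9008 and 3309 normalized counts in NFD replicates 1 to 3 and at 117, 252 and 1254 in HFD replicates 1 to 3, and miR-216b at 854, 6076 and 3049 and at 94.1, 202 and 964. miR-375 and miR-7a-5p, which are abundant in hormone-producing islet cells, were high in NFD replicate 2 and HFD replicate 3, which within each diet were also the highest libraries for miR-217 and miR-216b: miR-375 was at 993 and 1251 there and between 63.1 and 97.7 in the other libraries, and miR-7a-5p at 290 and 367 there and between 3.87 and 16.8 in the others.

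NFD replicate 2 was low in several miRNAs of different kinds. Of the 257 sequences 59 were lowest there, where an even share over the libraries would be 43, and 9 were below 0.5 times the next lowest library. Of the 8 sequences of the blood and immune cell list other than miR-144 and miR-451, 5 were lowest there and 2 below 0.5 times the next. miR-155 was at 174 there and between 908 and 2985 in the other libraries, miR-146b at 3571 against 17183 to 31830, and miR-462, which responds to infection in fishes, at 8710 against 17791 to 29095. Outside the immune miRNAs, miR-458-3p was at 781 against 2287 to 4450 and miR-200b-3p at 2105 against 3202 to 6943, while the immune miR-150-5p was at 4575 there and between 3111 and 5408 in the others. let-7d-5p was at 2535 and 2258 in HFD replicates 2 and 3 and between 497 and 664 in the others, and the aca form of miR-125a-5p at 2292 and 2256 against 432 to 571. The abundant form of miR-125a, at 18728 ± 1750 in NFD and 20158 ± 2872 in HFD (SD, n = 3), showed no such step. Candidate PC-5p-4613_1561 was at 557 and 661 in NFD replicates 2 and 3 and between 1.94 and 3.22 in the other libraries. These steps between libraries were picked after their values were seen, and no test was run on them beyond the comparison of diets.

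All tests of explanations below were chosen after the results were seen. The 7 sequences of miR-144 (2) and miR-451 (5) were all lower in HFD, with a median log2 difference of -1.19. They are forms of miRNAs that are transcribed together, so they are not independent. miR-2188-5p and miR-2188-3p, at -1.05 and -1.24, were not part of these tests. The tables argue against a scaling factor given to each library, which would move all rows alike. The median of the 7 sequences lay lower than that of all 257 sequences (0.03) by a difference of -1.22. Some gap was known beforehand, since members of both families had passed as lower and the median of all sequences lay near 0. Without NFD replicate 3, which had the highest upper estimate of depth, the median of the 7 sequences was -1.07, so the size of the fall did not rest on that library. The sequences that passed had all HFD libraries below all NFD libraries, so some fall had to remain without it. No row passed the threshold without that library (limma). A lower share of every cell type other than hepatocytes is argued against too: the endothelium and connective tissue list had a median of -0.12, and the mean level of the red cell sequences fell by 1.2 relative to it, against an SD of 0.26 within diets. Other cell types did not all stay level, since the muscle list had a median of -0.61, the pancreas list -0.44 and the epithelium list 0.17, so a lower share of some of them stays open. Less blood in the HFD samples stays open, and so does a change of the red cells with the diet, which may act alone or with it and was not tested. If both miRNAs came only from blood, which was not tested, less blood alone should lower both by the same factor. miR-144 (mean of 2 sequences) fell by 0.93 more than miR-451 (mean of 5 sequences). Of 3 versions of this difference the 95% interval excluded 0 for the average (-1.79 to -0.06) and for miR-144-5p (-1.16 to -0.08). It did not for miR-144-3p (-2.49 to 0.11), and the test was changed more than once after its values were seen.

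Some mRNA identifiers alone in their component followed the diet fully: 14 were at 10 RPKM or more in every HFD library and at 0 in every NFD library, and 17 the reverse, 31 in all. The tables argue against library depth, which differed by 1.27-fold at most. Reads moving between copies within a component are no explanation for identifiers alone in theirs, though copies that the assembly split into different components were not tested. A source other than the liver cells, such as a feed organism, parasite or virus that reached all libraries of a diet, could give such a step. It cannot be told apart from a response of the fish or a difference between the families of fish in each diet. The median CV over the libraries that held the identifier was 13.1%. It was 17.2% over the HFD libraries for the 2349 lone identifiers at 10 RPKM or more in every library. Of the 14 HFD-only identifiers, 7 were at 100 RPKM or more in every HFD library. Their HFD means ran from 493 to 1131 RPKM, with SDs from 10.6 to 57.4. They were not compared with other lone identifiers at such levels. Without sequences the origin stays open. Of the 10 splits of the 6 libraries 3 against 3, 1 gave as many, the real one, and the highest other gave 2, while identifiers that share a component with others gave 39 for the diets and 45 for another split; 10 splits are too few for a share under 0.05.

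The same 10 splits were refitted for the counts of calls, and again they are too few for a share under 0.05. The diets gave 7 miRNA rows and the highest other split 1, so 1 of the 10 gave as many. The diets gave 71 mRNA identifiers and the highest other split 49, with 1 of the 10 giving as many. For the lists 8 of the 10 splits called at least 1 list by camera, the number the diets gave, and the highest other split called 2.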
